A study of Mus musculus with 6 samples.

How the data were processed

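Genomic DNA from brain tissue of 6 mice, 3 with ischemic injury and 3 controls, was enriched for 5hmC by selective chemical labelling and capture (hMe-Seal) and made into sequencing libraries by an Illumina ChIP-seq protocol, per the labels' protocols. The submitters' processing notes name CASAVA 1.4, Bowtie 0.12.9, MACS 1.4.2 and the mouse genome build mm9, without settings. The authors deposited 1 peak list per group, with a position, a peak name of the kind MACS writes, and a score for each peak. The lists have no header. The score starts at 50 in both lists and is taken here to be the usual score of this MACS version, -10 times the base-10 logarithm of the p-value. Whether the reads of the 3 mice in a group were pooled before peak calling, whether an input library served as control, and how many reads went in are not given in the sources used here. A deeper library gives more peaks and higher scores at the same enrichment, so scores were used to describe and rank peaks within their own list. A common cut on score was used only in the stricter thresholds named below and in a count of the highest scores. Where scores of both lists are printed together, each is on the scale of its own list.

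Each list was assigned to its group by the name it shares with the 3 samples of that group. All computations were made from the deposited peak positions and scores with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Positions are printed counting from 1. On chromosome 7 the peaks reach 152.5 Mb, and 97 control-list and 288 injury-list peaks lie beyond the last gene of that chromosome in a GRCm38 gene table, so the positions were not matched to that table. No gene annotation of mm9 was used here, and positions were not converted between builds. For this reason the planned comparisons by genomic feature and by 24 fixed gene lists were not made, and regions are given by position only, with no gene or exon named.

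Peaks were counted as shared when they overlapped by at least 1 bp. Sharing was set beside 1000 random placements, in which the other list was shifted by 1 random distance per chromosome, wrapping around between the first and last peak; 100 such placements were drawn for the overlap of 50% of both peaks. Nearness was the share of peaks with another peak of the same list within 5 kb, beside 1000 sets of the same widths with random midpoints. Peak density was taken per Mb between the first and last peak of either list. Windows were 1 Mb long, and a peak belonged to the window of its midpoint. The overlap functions were tested on simulated peaks: of the control-list peaks that were moved by a known distance, 100% were found, and on chromosome 19 the shared peaks had 0 mismatches with a direct comparison of all pairs.

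With 1 list per group there is no spread between mice, so no test of the conditions was made and no p-value is given. Shares carry exact binomial (Clopper-Pearson) 95% intervals, counts exact Poisson intervals and ratios of peak numbers an exact conditional binomial interval. Neighbouring peaks are not independent, so these intervals are too narrow for regions that come in groups. The regions named were set by a rule before the data were examined: the 5 highest-scoring peaks of each list, the 5 highest-scoring peaks of each list without overlap, and the 3 windows of 1 Mb with the highest and the lowest difference in peak number. Ties were broken by peak width or by the total number of peaks, which the rule had left open, and the widest control-list peak was added after its values were seen. The alternatives fixed at the same time were stricter score thresholds at the 50th and 75th percentile of the control list (79.7 and 120.4), merging of peaks within 1 kb, autosomes alone, an overlap of 50% of both peaks or nearness within 1 kb as sharing, covered bases in place of peak numbers, only the peaks without overlap, a 1 kb limit for nearness, and an injury list reduced to as many highest-scoring peaks as the control list has. Local shifts of 50 kb to 1 Mb, and the control median score as a threshold for 1 list alone, were added later.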

Results

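5-Hydroxymethylcytosine (5hmC) is the oxidised form of 5-methylcytosine that TET enzymes make, and it is abundant in brain DNA. It was mapped across the genome in brain tissue of C57BL/6 mice after ischemic injury and in matched control tissue, with 3 mice per group. The assay was hMe-Seal, in which a chemically modified sugar is placed on each 5hmC base so that the DNA fragments that carry it can be captured and sequenced. The data used here were 2 lists of 5hmC-enriched regions (peaks), 1 per group, on the mouse mm9 genome. No values for single mice, read numbers or sequencing depths were used, so neither list has a replicate error, and the depth behind each list is unknown. No difference between the lists could be set against the spread between mice. The 95% intervals given with counts (exact Poisson), shares (exact binomial) and ratios of counts (exact conditional binomial) cover counting error only, and they treat each peak as an independent count.

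The first comparison asked how much of the genome was enriched for 5hmC in injured and in control brain. The injury list held 53374 peaks (95% interval 52922 to 53829) and the control list 20583 (20303 to 20866), a ratio of 2.59 (2.55 to 2.64). The injury-list peaks covered 133.7 Mb and the control-list peaks 63.1 Mb, a ratio of 2.12. Control-list peaks had a median width of 2654 bp (quartiles 2004 and 3587 bp), and injury-list peaks a median width of 2056 bp (1536 and 2900 bp). The order turned with the injury list reduced to its highest-scoring peaks, as many as the control list has, whose median width was 3053 bp. Width rose with score in the injury list, from a median of 1433 bp in the lowest-scoring 10% to 4737 bp in the highest. Choosing by score could thus give the wider median by itself. In regions where exactly 1 peak of each list overlapped, 12970 in all, the median widths were 2652 bp in the control list and 2593 bp in the injury list, and the injury-list peak was the narrower in 53.8% of them (53.0 to 54.7%). The peak caller's score, which is the authors' own value for each peak, started at 50 in both lists and had a median of 79.7 in the control list and 87.3 in the injury list. The number of peaks that a caller reports, and each score, depend on the number of reads, so the ratio of peak numbers is a property of these lists and not a measure of total 5hmC.

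Along the genome the injury list held more peaks nearly everywhere. Of the 1850 windows of 1 Mb that held any peak, 1683 (91.0%) had more injury-list than control-list peaks, 75 had equal numbers and 92 had more control-list peaks. The largest surpluses of injury-list peaks were on chromosome 11 from 113 to 114 Mb, with 162 injury-list and 66 control-list peaks, on chromosome 4 from 150 to 151 Mb, with 138 and 42, and on chromosome 4 from 139 to 140 Mb, with 138 and 48. The injury list made up 71.1% (64.7 to 76.9%) of the peaks in the chromosome 11 window, 76.7% (69.8 to 82.6%) in the chromosome 4 window from 150 Mb and 74.2% (67.3 to 80.3%) in the chromosome 4 window from 139 Mb. The value for both lists over the whole genome was 72.2% (71.8 to 72.5%), so the chromosome 11 and chromosome 4 windows were peak-rich in both lists, and their composition did not differ from that of the genome by more than counting error. After peaks within 1 kb were merged, their surpluses of 96, 96 and 90 peaks were 51, 60 and 47. Windows with more control-list peaks had a surplus of at most 2 peaks, which 7 windows reached. The 3 of these with the most peaks in all were on chromosome 1 from 15 to 16 Mb, with 4 control-list and 2 injury-list peaks, on the X chromosome from 70 to 71 Mb, with 3 and 1, and on chromosome 2 from 54 to 55 Mb, with 2 and 0. Such small counts do not separate these windows from chance. A total of 236 windows held injury-list peaks and no control-list peak, and 69 held control-list peaks and no injury-list peak.

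All 19 autosomes had more injury-list than control-list peaks, and the densest and the sparsest autosome were the same in both lists. Chromosome 11 had the most peaks per Mb between the first and last peak, 15.3 in the control list and 35.6 in the injury list. Chromosome 3 had the fewest among the autosomes, 4.33 in the control list and 13.9 in the injury list. The injury list made up from 69.5% of the peaks of both lists on chromosome 17 (68.1 to 70.9%) to 76.7% on chromosome 6 (75.2 to 78.1%). High values were also found on chromosome 3 (76.3%, 74.6 to 77.9%), chromosome 14 (75.9%, 74.1 to 77.7%) and chromosome 13 (75.7%, 73.9 to 77.4%). Low values were found on chromosome 11 (69.9%, 68.8 to 71.1%), chromosome 5 (70.4%, 69.3 to 71.5%) and chromosome 4 (70.4%, 69.3 to 71.6%). The peak-poor chromosomes 3, 6, 13 and 14 thus lay above the genome-wide 72.2%, and the peak-rich chromosomes 4, 5, 11 and 17 below it, each by more than counting error. Chromosome 1, also among the 5 sparsest, lay above it as well (74.3%, 72.9 to 75.7%). Chromosome 15, also among the 5 densest, had an interval that takes in the genome-wide value (71.2%, 69.7 to 72.6%). With the reduced injury list, the injury share on the 5 autosomes with the fewest peaks per Mb exceeded that on the 5 with the most by 0.71 percentage points (bootstrap interval -0.46 to 2.09), against 5.43 (4.45 to 6.46) with all peaks, 5.18 (3.85 to 6.46) with both lists at or above the control median score and 6.33 (5.25 to 7.50) in covered bases. The shares themselves were 50.5% and 49.7% with the reduced list and 75.7% and 70.3% with all peaks. Points at such unlike levels are not equal effects.

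The X chromosome had far fewer peaks than every autosome in both lists. It held 28 control-list peaks (18.6 to 40.5) and 33 injury-list peaks (22.7 to 46.3), or 0.17 and 0.21 peaks per Mb. The autosomes together had 8.67 control-list and 22.5 injury-list peaks per Mb, which is 49.8 and 109.7 times the density on X. The sparsest autosome, chromosome 3, still had 24.8 times the density of X in the control list and 67.8 times in the injury list. The injury list made up 54.1% of the X peaks (40.8 to 66.9%), below the lowest autosome, though after peaks within 1 kb were merged its upper bound of 67.3% passed the lowest autosome, chromosome 4 at 66.6%. Only 7 of the 28 control-list peaks on X (25.0%, 10.7 to 44.9%) overlapped an injury-list peak, compared with 81.3% (80.8 to 81.9%) on the autosomes. Of the 33 injury-list peaks on X, 7 (21.2%, 8.98 to 38.9%) overlapped a control-list peak, an interval that takes in the 34.2% of the autosomes. Within the control list the X peaks had a median score of 127.2 against 79.6 on the autosomes and a median width of 1779 bp against 2655 bp. Within the injury list the X peaks had a median score of 75.1 against 87.3 on the autosomes and a median width of 1649 bp against 2056 bp. Neither list had a peak on the Y chromosome.

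**Figure D1:**
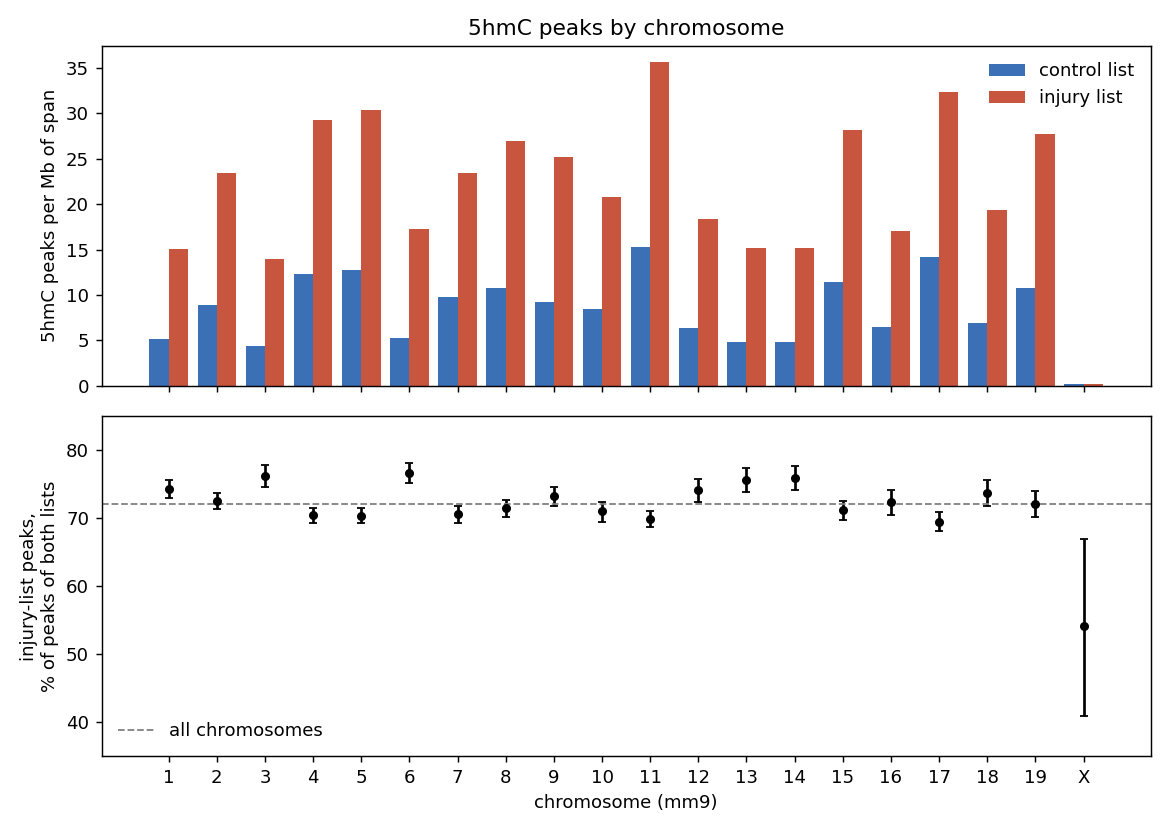
The upper panel shows 5hmC peaks per Mb between the first and last peak of each mm9 chromosome as bars from 0, for the control list (blue) and the injury list (red), each list standing for 3 mice. The lower panel shows injury-list peaks as a percentage of the peaks of both lists (points, with exact binomial 95% intervals; the axis does not start at 0) and the genome-wide 72.2% (dashed line); the X chromosome lies at 54.1%, and the 19 autosomes lie between 69.5% and 76.7%.

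The next comparison asked whether 5hmC was enriched at the same places in injured and control brain. Of the control-list peaks, 16728 of 20583 (81.3%, 80.7 to 81.8%) overlapped an injury-list peak by at least 1 bp. Of the injury-list peaks, 18233 of 53374 (34.2%, 33.8 to 34.6%) overlapped a control-list peak, which left 35141 peaks in the injury list alone and 3855 in the control list alone. When the other list was moved along each chromosome by a random distance 1000 times, the overlap of the control list had a median of 11.6% (range 8.59 to 17.3%) and that of the injury list 4.98% (3.60 to 7.61%). The observed sharing was 7.01 times the median of these placements for the control list and 6.86 times for the injury list. Moves of only 50 kb to 1 Mb, which keep peaks within their peak-rich or peak-poor surroundings and which were added after the lists were seen, gave medians of 29.5% and 13.0%, and the observed sharing was 2.76 and 2.64 times these. With the injury list reduced to the length of the control list, 57.97% of control-list and 57.90% of injury-list peaks were shared. With the full lists and an overlap of 50% of both peaks, 63.5% of control-list and 24.5% of injury-list peaks were shared, 16.8 and 17.0 times the median of 100 random placements.

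In each list the share of peaks found in the other list was larger among higher-scoring peaks. In the lowest-scoring 10% of the control list 67.5% (65.4 to 69.5%) overlapped the injury list, and in the highest-scoring 10% 95.9% (94.9 to 96.7%), which left 85 of 2059 peaks without a counterpart. In the injury list the share ran from 12.8% (11.9 to 13.7%) in the lowest-scoring 10% to 84.9% (83.9 to 85.8%) in the highest, where 808 of 5338 peaks had no counterpart. Peaks of the control list alone had a median score of 64.2 and a median width of 2090 bp, against 84.99 and 2807 bp for its shared peaks. Peaks of the injury list alone had a median score of 75.5 and a median width of 1893 bp, against 139.9 and 2577 bp for its shared peaks. On the autosomes the shared part of the control list ranged from 74.6% on chromosome 13 to 84.2% on chromosome 8, and that of the injury list from 25.7% on chromosome 6 to 40.4% on chromosome 17.

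**Figure D2:**
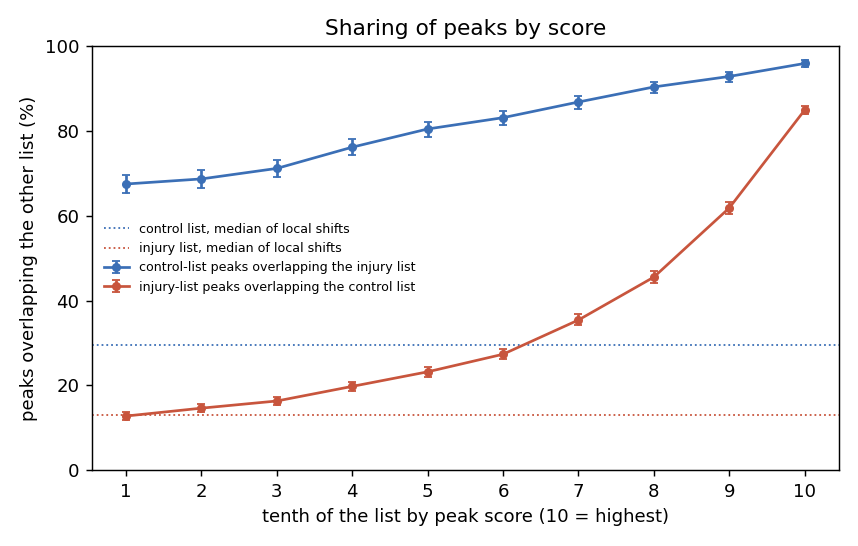
Percentage of peaks that overlap the other list by at least 1 bp (y axis) in 10 equal parts of a list by the authors' peak score (x axis, 10 is the highest), for the control list (blue) and the injury list (red), with exact binomial 95% intervals. Dotted lines give the median over local random shifts, 29.5% for the control list and 13.0% for the injury list; the sharing goes from 67.5% to 95.9% in the control list and from 12.8% to 84.9% in the injury list.

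The highest-scoring peaks of each list were enriched in both groups. The control list was led by a peak of 8.22 kb on chromosome 10 (79434926 to 79443150, score 3179.66), which an injury-list peak of 8.60 kb overlapped (79434470 to 79443067, score 2386.4, at rank 3 in that list). The other 4 leading control-list peaks were on chromosome 7 (6082860 to 6085437), chromosome 15 (76002166 to 76015008), chromosome 5 (144008494 to 144019122) and chromosome 8 (72402761 to 72410809), with scores of 3103.86 for the chromosome 7 peak and 3100 for the others, and each overlapped at least 1 injury-list peak. The best scores of those injury-list peaks were 254.2, 1087.72, 1001.26 and 754.58, in the same order and on the scale of their own list. The score of 3100 or more was reached by 13 control-list peaks and 1 injury-list peak, so that equal scores were ordered by width. The highest score in the injury list, 3100, belonged to a peak of 5.40 kb on chromosome 6 (47596379 to 47601782), which overlapped a control-list peak of 6.15 kb (score 3100). The fifth injury-list peak by score lay on chromosome 17 (30878538 to 30892694, score 1941.24) and overlapped a control-list peak as well (score 679.93).

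The remaining 2 leading injury-list peaks, with scores of 2479.33 and 2350.43, lay side by side on chromosome 2 (77781424 to 77784103 and 77730181 to 77781224), and the second of them, at 51.0 kb, was the widest peak of the injury list. Both fell inside the widest peak of the control list, which ran for 79.7 kb (77710619 to 77790297, score 240.99). A total of 9 injury-list peaks lay on this control-list peak and covered 94.96% of it. Over the genome 2355 control-list peaks (11.4%) overlapped 2 or more injury-list peaks, and 987 injury-list peaks (1.85%) overlapped 2 or more control-list peaks.

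**Figure D3:**
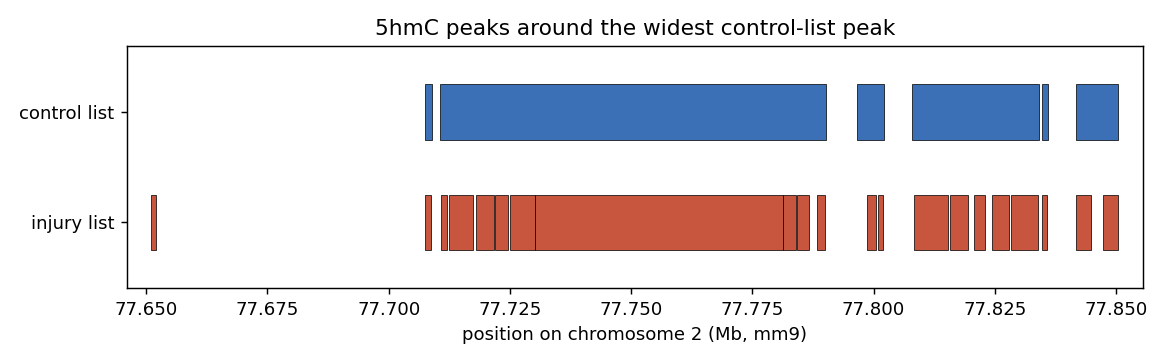
Peaks of the control list (upper row, blue) and the injury list (lower row, red) by position on mm9 chromosome 2 in Mb, around the widest control-list peak of 79.7 kb; each box is 1 peak drawn to scale. The 9 injury-list peaks on it, the widest of 51.0 kb, cover 94.96% of it.

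Regions found in only 1 group included high-scoring ones. The injury-list peaks with the highest scores and no control-list overlap were broad: chromosome 4 (46624740 to 46634479, 9.74 kb, score 964.29), chromosome 8 (111421659 to 111433395, 11.7 kb, score 834.77), chromosome 11 (113592942 to 113601481, 8.54 kb, score 793.02), chromosome 17 (30643058 to 30658120, 15.1 kb, score 753.85) and chromosome 10 (80756898 to 80767242, 10.3 kb, score 708.12). All 5 lay close to control-list peaks, at distances of 1.26 kb on chromosome 11 to 6.28 kb on chromosome 17. The control-list peaks with the highest scores and no injury-list overlap were on chromosome 11 (11924040 to 11927600, 3.56 kb, score 820.54), chromosome 6 (49344910 to 49346437, 1.53 kb, score 657.13), chromosome 18 (13130787 to 13133235, 2.45 kb, score 507.33), chromosome 7 (20106744 to 20114756, 8.01 kb, score 486.38) and chromosome 4 (99714303 to 99716186, 1.88 kb, score 449.12). The nearest injury-list peak was 167.5 kb from the chromosome 11 peak, 56.9 kb from the chromosome 6 peak and 39.8 kb from the chromosome 18 peak, but under 1 kb from the peaks on chromosomes 7 and 4. These named regions come from 1 list per group, and whether each mouse of a group showed them is not known.

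Peaks of both lists lay closer together than peaks placed at random over whole chromosomes. In the control list 49.0% of peaks (48.3 to 49.7%) had another control-list peak within 5 kb, against a median of 14.7% (range 13.7 to 15.9%) for 1000 sets of the same size and widths placed at random. In the injury list the share was 70.2% (69.8 to 70.6%) against 30.2% (29.6 to 31.1%) at random. Nearness was thus 3.34 times the random median in the control list and 2.32 times in the injury list. Random midpoints do not keep peak-rich and peak-poor surroundings, and no local placement was tried for nearness. Splitting of broad regions into several peaks can also put peaks close together. These folds therefore do not measure grouping of 5hmC itself. With the injury list reduced to its highest-scoring peaks, as many as the control list has, 56.6% of its peaks (55.9 to 57.3%) had another within 5 kb, 3.68 times the random median. The order of the 2 lists by this fold thus depends on which injury-list peaks are kept. That choice changed length and score together, so the move cannot be put down to length alone. With a limit of 1 kb the shares with a neighbour were 20.9% in the control list and 37.7% in the injury list.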

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

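The injury list was the longer one under every alternative tried, except where it was reduced to the length of the control list. At the control median score the lists held 10292 control and 30324 injury peaks (ratio 2.95), and at the 75th percentile 5146 and 16931 (ratio 3.29); merging peaks within 1 kb gave a ratio of 2.27. Since scores grow with depth, a common score threshold does not put the lists on equal terms. Sharing moved with the definition. An overlap of 50% of both peaks left 63.5% of the control list and 24.5% of the injury list shared (16.8 and 17.0 times the median of 100 random placements), and nearness within 1 kb gave 84.6% and 40.6%. At the control median score the shares were 80.4% and 29.7%, with folds of 9.52 for the control list and 9.44 for the injury list. With lists of equal length they were 57.97% and 57.90%, with folds of 9.98 and 9.91. Shifts of 50 kb to 1 Mb, added after the data were seen, lowered the folds to 2.76 and 2.64. Peaks without overlap had median widths of 2090 bp (control) and 1893 bp (injury) and median scores of 64.2 and 75.5, and the reduced injury list had a median width of 3053 bp and a median score of 164.3, so the order of the lists by median width reversed. The reduced list was chosen by score, and width rose with score, so this reversal is not an effect of length alone. On X the injury share fell to 39.4% (22.9 to 57.9%) at the control median score, with 20 control and 13 injury peaks, and lay below all 19 autosomes at that threshold, after merging and in covered bases, but after merging its upper bound, 67.3%, passed the lowest autosome, chromosome 4 at 66.6%. Nearness within 1 kb was 20.9% in the control list and 37.7% in the injury list (2.70 and 2.42 times random), and within 5 kb in the reduced injury list 56.6% (3.68 times). The surplus of the named windows on chromosomes 4 and 11 kept its direction, and that on chromosome 2 from 54 Mb ended (difference 0) at the control median score. No paired analysis was possible because each group has 1 peak list and no values per mouse; for the same reason no mouse could be left out and no other split of the mice was tried. The alternatives planned for genomic features and gene lists were not run, for want of an annotation of the build. Depth is unknown, so a peak missing from a list was not detected there and is not shown to be absent.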

Other observations

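The tests of splitting, depth, X-peak scores, the Y chromosome and peak density at the control median score, and the distances between the lists, were chosen after the results they bear on had been seen, and the tests on matched X peaks and the other tests on peak density before their own results.

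Peaks found in only 1 group lay near peaks of the other group more often than randomly shifted peaks did, although most of those in the injury list had no control-list peak within 10 kb. Of the 35141 injury-list peaks without overlap, 15881 (45.2%, exact binomial 95% interval 44.7 to 45.7%) were within 10 kb of a control-list peak, against a median of 31.6% (29.7 to 33.8%) in 200 shifts of 50 kb to 1 Mb and 14.6% (12.3 to 20.5%) in 200 shifts along whole chromosomes. Of the 3855 control-list peaks without overlap, 2506 (65.0%, 63.5 to 66.5%) were within 10 kb of an injury-list peak, against 50.0% (46.7 to 53.1%) and 26.1% (22.3 to 30.6%). Within 5 kb the share of the injury-list peaks was 30.6%.

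A total of 7 regions of the X chromosome were enriched in both groups. They lay at positions 11578124 to 11579309 (score 52.89 in the control list, 65.98 in the injury list), 11713957 to 11718104 (302.39 and 138.35), 13062106 to 13064872 (1218.98 and 55.84), 17089784 to 17091611 (476.71 and 75.11), 34702533 to 34704186 (69.6 and 76.69), 70598649 to 70599997 (198.49 and 78.9) and 154256275 to 154258126 (54.36 and 129.4), each score on the scale of its own list.

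The longer injury list is the first pattern. Splitting of the same regions into more peaks is argued against as the whole cause, because the ratio of peak numbers was still 2.27 after peaks within 1 kb were merged, and the covered bases differed 2.12-fold. Greater depth or sensitivity behind the injury list stays open for the autosomes: 96.1% (95.1 to 96.9%) of the highest-scoring 10% of autosomal control-list peaks were found again, and 72.9% (71.5 to 74.3%) of the autosomal control-list peaks not found lay below the median score. A gain of 5hmC after injury on top of the control pattern could give the same values, so depth and gain cannot be told apart on the autosomes without read numbers and single mice. The scores, which grow with depth, went both ways. A score of 3100 or more was reached by 13 control-list peaks and only 1 injury-list peak. The median score was 79.7 in the control list and 87.3 in the injury list. The settings of the peak calling are not given, so the scores do not decide.

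The X chromosome is the second pattern, with an injury share of 54.1% and 25.0% of control-list peaks shared. Control-list X peaks were not weak, with a median score at percentile 77.1 of their list (bootstrap interval 52.4 to 89.0), and autosomal control-list peaks matched to them in score and width were shared at a median of 75% (57.1 to 85.7% over 1000 draws), above the upper bound of 44.9% for X. At the control median score the injury share on X was 39.4%. Its upper bound of 57.9% lay below the lowest lower bound of an autosome, 69.4%. With all peaks merged within 1 kb the upper bound of the injury share on X, 67.3%, passed chromosome 4 at 66.6%. Matching also on the number of other control-list peaks within 1 Mb gave 60.7% shared (42.9 to 78.6%). The 25.0% on X lay below that range of draws, each of as many peaks as the control list has on X. By the rule set beforehand the test could not tell, because the range reaches the upper bound of 44.9% for X. These matched peaks had a lower median score (108.2, against 127.2 on X), and sharing rose with score in the control list. The values therefore argue against sparse surroundings, counted by control-list peaks, as the whole cause of the low sharing. A part in it stays open. A depth difference alike on every chromosome is argued against as the whole cause of the low sharing on X. The 25.0% lay below the draws of both matches, and the matched autosomal peaks came from the same lists. For the injury share on X such a depth difference stays open. A common score threshold does not put the lists on equal terms, and after merging the upper bound on X passed chromosome 4. A different sex makeup of the groups stays open, because the labels used here give no sex and the 0 peaks on the Y chromosome decide nothing. The injury itself, which was not tested, stays open as well.

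The higher injury share on peak-poor autosomes is the third pattern: 75.7% on chromosomes 1, 3, 6, 13 and 14 against 70.3% on chromosomes 4, 5, 11, 15 and 17, a difference of 5.43 percentage points (1000 bootstrap draws of 1 Mb windows, 4.45 to 6.46). It is not produced by ranking chromosomes on the same counts, since windows classed by their neighbours alone differed by 6.05 points (4.67 to 7.41), nor by joining of injury-list peaks in dense regions, since covered bases differed by 6.33 points (5.25 to 7.50). Extra weak peaks of the injury list stay open. The difference was 3.23 points (2.12 to 4.33; shares of 61.7% and 58.5%) with the injury list alone cut at the control median score. With the injury list reduced to the length of the control list it was 0.71 points (-0.46 to 2.09; shares of 50.5% and 49.7%). With the control list alone cut it was 5.44 points (4.38 to 6.59; shares of 87.4% and 82.0%). The level of the injury share moved with each cut, and points at unlike levels are not equal effects. The 5.44 points therefore do not show an unchanged pattern. With both lists cut at the control median score the difference was 5.18 points (3.85 to 6.46), but the injury list was then still 2.95 times as long, so this value does not decide. A difference in depth, for which read numbers are missing, and the injury itself, which was not tested, stay open.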
